A study of Gallus gallus with 7 samples.

How the data were processed

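Single-cell RNA sequencing was done on cells of chick embryo hearts (Gallus gallus) sorted for a nuclear red fluorescent protein, H2B-RFP, with which cardiac neural crest cells had been marked by a retrovirus. The libraries are 10x Genomics Chromium 3′ gene expression libraries, per the labels. The 7 libraries comprise sham-operated hearts at days 4, 5, 6 and 7 (4 libraries, replicates 1 to 4) and hearts after left atrial ligation at days 4, 5 and 6 (3 libraries, replicates 1 to 3). Each age and treatment thus has 1 library. A ligated library of day 7 was not analysed here. No label says how many embryos went into a library, so every p-value measures only the spread between these libraries.

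The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger. The version is 9.0.0 per the file headers and 5.0.1 per the submitters' processing notes. Per the labels, the authors then worked in Seurat, and no output of that step was used. The genome build and the annotation are not given in the sources used here. Genes are named by the deposited identifiers and symbols. Of 17008 features, 3940 have no symbol and 12 symbols belong to more than 1 feature. An added feature, H2BRFP, counts the label transcript. Every deposited barcode has at least 500 UMIs.

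The deposited counts held 21190 barcodes. Barcodes with at least 500 detected genes and at most 20% of UMIs from the 13 mitochondrially encoded genes were retained. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 0.06, and removed, which left 19227 cells. The caller did not work on these data: it called 1 barcode or none in the 5 largest libraries, 10 of 259 in the day 4 sham library and 19 of 61 in the day 5 sham library. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes within libraries were taken, with mitochondrial, ribosomal and globin genes left out. Clustering used 30 principal components, 15 neighbours and the Leiden method at resolution 1, without integration. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.

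The 28 clusters were named from 14 marker lists. A cluster took the class with the highest mean log2 fold of its markers if that was at least 1, and a median globin share of at least 30% made it erythroid-like. This gave 15 erythroid-like clusters. Clusters 1, 2 and 4 had low UMI counts and no marker among their leading genes and stayed unnamed. Class names describe transcripts only, hence the ending "-like". Shares carry exact Clopper-Pearson 95% intervals, and CPM values (a gene's UMIs scaled by all UMIs of the summed cells) carry exact Poisson 95% intervals. Where a count is 0, the upper limit is that of 3 counts. These intervals and limits cover counting error only.

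For tests, raw counts were summed over the cells of each library. Genes were filtered with filterByExpr, normalised with TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. The p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Ligated and sham libraries were compared over days 4 to 6 with day as a block, which pairs the 2 libraries of an age and leaves 2 residual degrees of freedom. The age slope was fitted over all 7 libraries with treatment as a covariate. All 21 gene lists were tested with camera of limma 3.58.1 at its preset correlation, and again with an estimated correlation and with fry. The 14 marker lists were tested in the same way as a separate family. Class shares were compared by an exact two-sided sign-flip permutation test over the 3 days, whose smallest possible p is 0.25. Single days have 1 library per treatment and so no test. There, list medians of log2 ratios were set against 10000 random lists of genes of like expression with at least 20 CPM. Random members were drawn independently from the same libraries. The position of a median among them thus reflects the spread between genes, not between libraries, and leaves out that genes of a list can move together.

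The comparisons, lists, cell filter and clustering were fixed before the data were examined, and so was the rule for the genes to name. In each tested comparison that rule takes genes with a symbol, a mean of at least 20 CPM, an adjusted p under 0.05 and, for ligation, the same sign in all 3 days. It names the 10 largest rises and 10 largest falls. If fewer than 5 genes pass, it names the 6 with the smallest p in each direction, reported as not passing. It also names up to 4 members of each list by highest mean CPM, and the 10 leading genes of each cluster. For each day it names the 5 largest and 5 smallest log2 ratios among genes with at least 100 CPM in 1 library and 10 UMIs in both. The age slopes in mesenchyme-like cells were added after the data were seen, and the thresholds for naming clusters were set after that point too.

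The within-class fit departs from the plan. The plan removed called doublets and required 20 cells of a class in each library. With doublets removed, the day 5 sham library has 10 mesenchyme-like cells, so no class would have been tested. Because the caller had failed, the sums for mesenchyme-like cells were made with called doublets kept, which gives 20 cells there. This choice was made after the cell counts were seen. At the clustering used it decides the outcome of that comparison, and both versions are reported.

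Recovery was tested on simulated data with the same libraries. For ligation, edgeR recovered 1.49% of genes changed by 1 log2 unit, 57.2% of those changed by 2 and 99.5% of those changed by 4 when all cells were summed. In mesenchyme-like cells it recovered 39.8%, 99.5% and 100%. False calls made up 4.55% and 5.91% of calls with edgeR, 3.87% and 5.74% with limma-voom, and 17.7% and 8.84% with the Wald test of DESeq2 1.42.0. On the real sums over all cells limma-voom called 2979 genes and edgeR 44, so the simulated rates need not hold for these libraries. For age slopes, false calls were 5.37% and 5.82% with edgeR, and 29.8% and 18.7% with DESeq2. In simulated lists moved by 1 log2 unit, camera at its preset correlation called 10 of 10, and with an estimated correlation it called 0 of 10. The second test therefore had no power in these simulations. The simulated genes varied independently of one another, whereas genes of the real lists can move together with the mixture of cells. Recovery by the preset test thus does not show that its p-values hold for the real lists. With all cells summed, fry called 0 of 10, and in mesenchyme-like cells it called 7 of 10.

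Alternatives tried were DESeq2 size factors, the DESeq2 Wald test, limma-voom with quality weights, no filter on low counts, no block for day, each day or library left out, counts thinned to the smallest library, other cell filters, doublets kept or removed, globin genes removed, erythroid-like and leukocyte-like cells left out, Leiden resolutions of 0.5 and 2, and expression centred per library.

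Total UMI counts were 10772261, 2205566, 20658025 and 70667416 in the sham libraries of days 4 to 7. They were 72959070, 120393593 and 54195309 in the ligated libraries of days 4 to 6. Barcodes over the mitochondrial limit made up 40.2%, 68.2% and 32.2% of the sham libraries of days 4 to 6, against 4.59%, 0.496% and 2.01% of the ligated ones. This sign of damaged cells goes with treatment at each of these ages and cannot be told apart from it. In the day 7 sham library such barcodes made up 0.744%.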

Results

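Transcripts were counted in single cells sorted from chick embryo hearts for a nuclear fluorescent label, H2B-RFP, carried by cardiac neural crest cells and their descendants. Ligation of the left atrium reduces the inflow of blood to the left side of the heart. Sham-operated hearts gave 4 libraries, at days 4, 5, 6 and 7, and ligated hearts gave 3, at days 4, 5 and 6, with 1 library per age and treatment. Kept cells numbered 249, 42, 801 and 5104 in the sham libraries in order of age, and 2769, 5793 and 4469 in the ligated ones. The median kept cell had 43284, 5395.5, 25074 and 10288 UMIs in sham libraries and 11956, 19492 and 11293 UMIs in ligated libraries. Barcodes in which over 20% of UMIs came from mitochondrial genes, a sign of damaged cells, made up 40.2%, 68.2% and 32.2% of the sham libraries at days 4 to 6. In the ligated libraries they made up 4.59%, 0.496% and 2.01%, and in the day 7 sham library 0.744%.

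The first question is which kinds of cell the sorted libraries held at each age. Mesenchyme-like cells, with collagen genes and TWIST1 on their marker list, fell into clusters 0, 5 and 6. None of the 10 leading genes of these clusters was on that list, and the mean log2 fold of cluster 5 was 1.01. The class changes with resolution. At resolution 2 it held 104 day 4 sham and 991 day 4 ligated cells, against 155 and 1147, and a cluster of 308 cells was named endothelium and endocardium-like. Leading genes of cluster 0 included CYTL1, AKR1D1 and SNAI1, and it held most mesenchyme-like cells at days 4 and 5. Cluster 6 was led by WNT11, CRISPLD1, EGFL6, ANGPT2 and MEOX2 and held 92.6% of them in the day 6 sham, 89.3% in the day 6 ligated and 97.4% in the day 7 sham library. Smooth muscle-like cells, led by ELN, FBLN5, TAGLN and ACTA2, were 607 cells in the day 7 sham library. That was 31.8% of its cells that were not erythroid-like (95% interval 29.7 to 34.0). In any other library it was at most 2.78%, which was 1 of 36 cells in the day 5 sham library. At resolution 0.5 no cluster took this name, and 1291 cells of the day 7 sham library lay in an unnamed cluster in which markers of another class led. Glia and Schwann precursor-like cells, led by SERAF, EDNRB, CHST8 and SOX10, neuron-like cells, led by NHLH2 and NEUROD1 or by GAL and CHRNA3, and epithelium-like cells, led by EPCAM, KRT24 and CLDN3, were also found. Small clusters of leukocyte-like cells (CSF1R, CD74) and cardiomyocyte-like cells (MYL3, ACTC1, TNNT2) held 78 and 49 cells. Unnamed clusters 1, 2 and 4 held 15.7%, 28.6%, 2.62% and 8.23% of kept cells in the sham libraries of days 4 to 7, and 23.1%, 0.621% and 0.336% in the ligated ones.

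Erythroid-like cells, with globin genes at their head, made up a large part of most libraries. Their share of kept cells was 0.402% in the day 4 sham and 10.0% in the day 4 ligated library, 14.3% and 94.5% at day 5, and 56.7% and 94.5% at day 6. In the day 7 sham library it was 62.6%. Different clusters held them in different libraries. In the day 6 sham library 434 of 454 lay in cluster 27, whereas the ligated libraries of days 5 and 6 filled clusters 11 to 17, 19, 20, 22 and 23, and the day 7 sham library clusters 24 to 26. The 95% interval was 5.43% to 28.5% in the day 5 sham library, which had 42 kept cells.

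**Figure D1:**
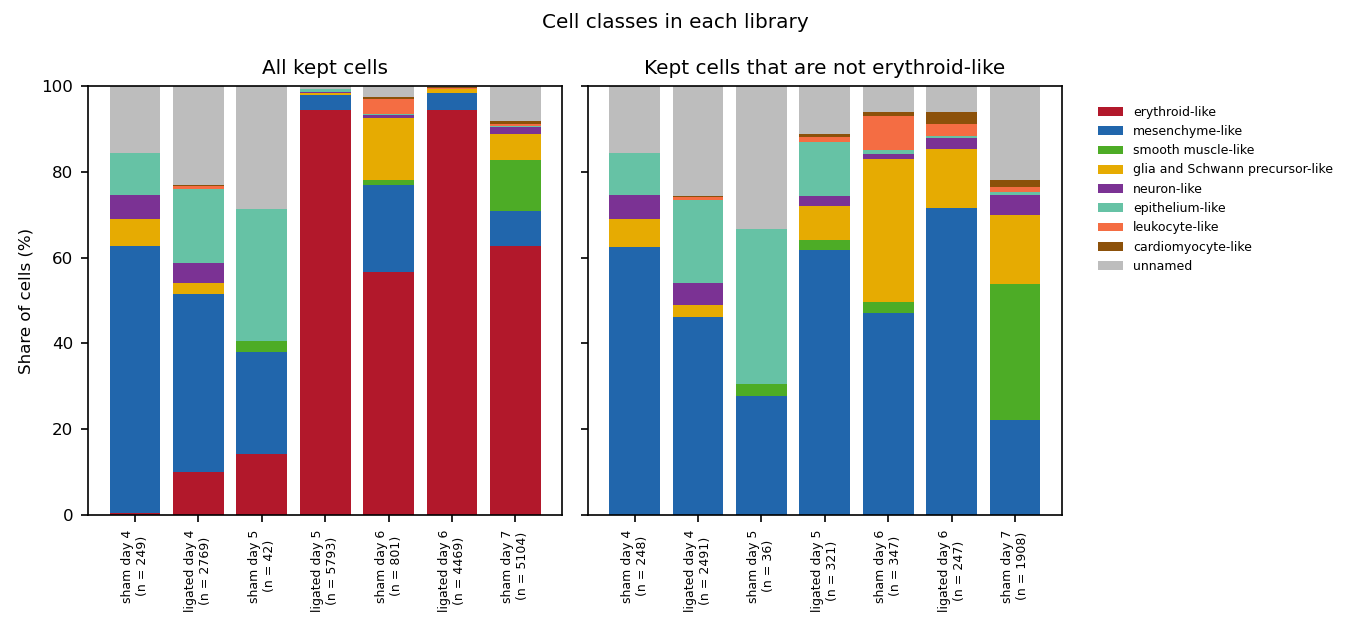
Stacked bars give the share of each cell class in each library in percent, over all kept cells on the left and over cells that are not erythroid-like on the right, with the number of cells under each bar. Erythroid-like cells reach 94.5% in the ligated libraries of days 5 and 6, and smooth muscle-like cells 31.8% of the other cells in the day 7 sham library.

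The transcript of the sorted label, H2BRFP, was measured in each class. In mesenchyme-like cells it stood at 57.7, 48.5, 49.97 and 45.4 CPM in the sham libraries of days 4 to 7, and at 40.2, 43.1 and 26.9 CPM in the ligated libraries of days 4 to 6. Smooth muscle-like cells of the day 7 sham library had 55.2 CPM. Glia and Schwann precursor-like cells had 66.3, 47.1 and 44.5 CPM in the sham libraries of days 4, 6 and 7, and 14.9, 69.1 and 26.3 CPM in the ligated libraries of days 4 to 6. Over all libraries, epithelium-like cells had 35.6 CPM, neuron-like cells 31.5, unnamed cells 20.05 and leukocyte-like cells 3.995 CPM, and cardiomyocyte-like cells had 0 UMIs in 49 cells, which allows up to 14.1 CPM. Erythroid-like cells had 0.539, 0.163 and 0 CPM in the ligated libraries of days 4 to 6, and 0.291 and 2.33 CPM in the sham libraries of days 6 and 7. The count of 0 UMIs in 4222 erythroid-like cells of the day 6 ligated library allows up to 0.0601 CPM. At least 1 H2BRFP UMI was seen in 53.7% of all mesenchyme-like cells, whose median depth was 29888 UMIs, and in 0.719% of erythroid-like cells, whose median depth was 13748.

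**Figure D2:**
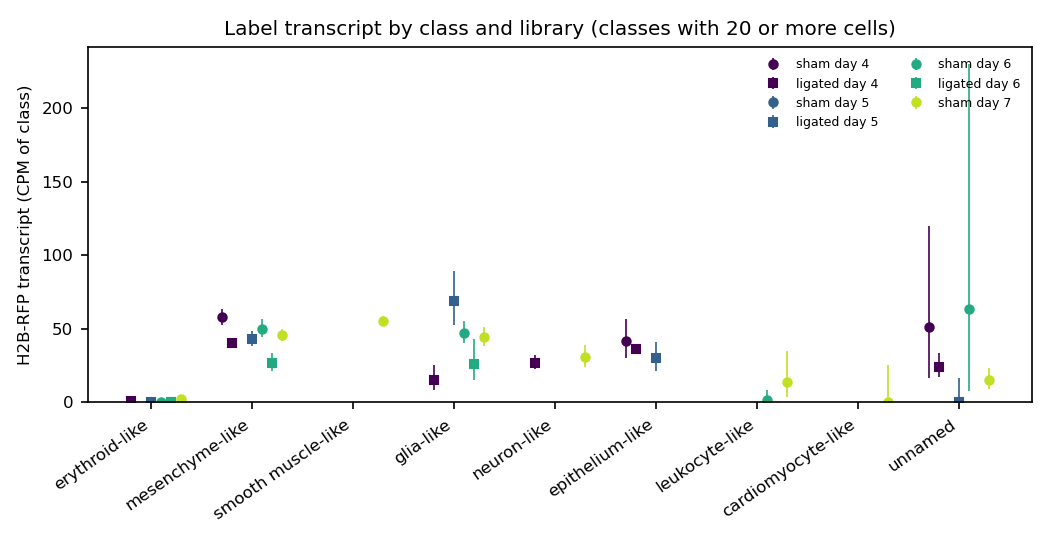
Points give H2B-RFP transcripts in CPM for each cell class of at least 20 cells in each library, with exact Poisson 95% intervals as bars. Mesenchyme-like cells lie between 26.9 and 57.7 CPM in the libraries drawn, and erythroid-like cells at or below 2.33 CPM.

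The second question is how the mixture of cells differed between ligated and sham hearts of the same age. The erythroid-like share was higher in the ligated library at all 3 ages, by 2.92, 4.56 and 2.57 logit units. Among cells that were not erythroid-like, smooth muscle-like cells were 0 of 248 (sham) and 2 of 2491 (ligated) at day 4. In the same order they were 1 of 36 (2.78%) and 8 of 321 (2.49%) at day 5, and 2.59% and 0 of 247 at day 6. The limit of the last is 1.21%. Their mean logit difference was −1.26, in which the negative sign of day 4 comes from the constant added to each count. Mesenchyme-like cells were 62.5% and 46.05% of such cells in the sham and ligated libraries at day 4, 27.8% and 61.7% at day 5, and 47.0% and 71.7% at day 6. These shares leave out called doublets, which took mesenchyme-like cells from 165 to 155 and from 20 to 10 in the sham libraries of days 4 and 5. In the ligated libraries of those days the numbers went from 1148 to 1147 and stayed at 198. Glia and Schwann precursor-like cells were 33.4% in the sham and 13.8% in the ligated library at day 6. Epithelium-like cells were 9.68% and 19.3% at day 4, and 36.1% and 12.5% at day 5. By the exact two-sided sign-flip permutation test the erythroid-like and smooth muscle-like differences had p = 0.25, the smallest that 3 pairs can give.

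Within the mesenchyme-like class, the day 4 libraries differed in make-up. Cluster 5, led by SMOC1, BMPR1B, GBX2, DLX5, DLX6, DLX2 and BARX1, held 491 of 1147 mesenchyme-like cells of the day 4 ligated library, or 42.8% (95% interval 39.9 to 45.7). It held 0 of 155 in the day 4 sham library, which allows a share of up to 1.94%, and 0 in the other 5 libraries. These counts depend on the clustering. At resolution 2 all 491 cells lay in a cluster of 556 of 991 mesenchyme-like cells of the day 4 ligated library (56.1%), 3 of 104 of the day 4 sham library (2.88%), 21 of 137 of the day 5 ligated library and 1 of 174 of the day 6 ligated library. At resolution 0.5 and with expression centred per library, nearly all mesenchyme-like cells of day 4 shared 1 cluster in both libraries. DLX genes pattern the pharyngeal arches. DLX5 stood at 352 CPM in cluster 5 and at 126 CPM in cluster 0 of the same library, HAND2 at 121 and 407 CPM. HOXA2 stood at 131 CPM in cluster 5 and 54.4 CPM in cluster 0, whereas HOXA3, of a more posterior identity, stood at 18.9 and 271 CPM and HOXD3 at 1.32 and 102 CPM.

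The third question is which genes differed between ligated and sham libraries of all 3 ages when all cells of a library were summed. Among the 10 largest rises were TAL1, a transcription factor of blood formation (3.80 log2 units), ANK1, which anchors the red cell membrane (3.48), and RFESD (ENSGALG00010013111; 4.93 ± 0.88 SE, adjusted p = 0.0340), a leading gene of erythroid-like clusters. They also included SLC30A10 (4.38), SUSD3 (4.19), RHOBTB3 (3.97) and EPAS1, a hypoxia-inducible transcription factor (3.25), likewise leading genes of erythroid-like clusters. MRC1 (3.99) and LUZP2 (3.14), also among the 10 largest rises, were not leading genes of a cluster. The falls that passed the rule were ACTG2 (ENSGALG00010020613), a smooth muscle actin (−3.31 ± 0.56 SE, adjusted p = 0.0271), and HEY2 (ENSGALG00010004892), a Notch target (−2.47 ± 0.46 SE, adjusted p = 0.0364). These genes had the same sign in all 3 days, although ANK1 differed by 0.03 log2 units at day 6, and the share of erythroid-like cells was higher in the ligated library on the same 3 days. By edgeR's quasi-likelihood test 44 of 13547 genes passed, 41 higher and 3 lower in ligated libraries, with 2244 at an unadjusted p under 0.05. With called doublets kept 7 passed, all of them higher, so ACTG2 and HEY2 lost their call. Without the day block 0 passed (1872). Without the day 4 pair 3760 genes passed, without the day 5 pair 15, and without erythroid-like and leukocyte-like cells 4.

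Lists of genes were tested in the same sums over all cells, so a change in the mixture of cells is included. Erythroid-like cells made up 94.5% of kept cells in the ligated and 14.3% in the sham library at day 5. At day 6 they made up 94.5% and 56.7%. A list that moved here cannot be told apart from this change of mixture. All 17 measured smooth muscle contractile genes were lower in ligated libraries (median −1.70 log2 units), and 2 fell, or 10 adjusted over the list alone. Neural crest regulators were lower in 24 of 26 (median −1.21), with none passing over all genes and 11 adjusted over the list alone. Notch pathway features were lower in 18 of 19 (median −1.10), the symbol HES6 belonging to a pair of features, with 1 that fell, or 5 adjusted over the list alone. NRARP, a Notch target, had −2.04 log2 units and an adjusted p of 0.0836. Extracellular matrix genes had a median of −0.91, and none passed in either way. G2 and M phase genes were higher in 33 of 33 (median 1.38), with none passing over all genes and 10 adjusted over the list alone. Ribosomal protein genes were higher in 68 of 69 (median 1.06), and all 5 globins were higher (median 2.503), with none passing in either way. At single days the ribosomal median was −0.30, 0.05 and 0.99 at days 4 to 6 and the globin median 3.71, 0.995 and −0.14. These day medians are of CPM without the TMM factors of the fit, which ranged from 0.36 to 1.76. Their signs are thus not on the scale of the fitted medians. By camera with its preset correlation the adjusted p was 1.5e-09 for smooth muscle, 2.9e-07 for neural crest, 2.4e-06 for Notch, 8.5e-06 for matrix, 1.5e-09 for G2 and M phase, 1.5e-09 for ribosomal genes and 9.8e-05 for globins. For these lists the adjusted p = 0.457 with an estimated correlation, except ribosomal genes (0.483). Of all 21 lists 16 passed with the preset correlation, 5 higher and 11 lower, and 0 with the estimated correlation or fry, whose lowest adjusted p was 0.0927 for Notch. Among marker lists, erythroid markers were higher in 7 of 7, with 1 that rose, or 2 adjusted over the list alone (median 2.52, adjusted p = 1.7e-06 by camera, adjusted p = 0.726 with an estimated correlation). Smooth muscle markers (−1.99), mesenchyme markers (−0.89) and endothelium markers (−1.23) were lower, with adjusted p values of 4.2e-07, 0.00392 and 0.000717 by camera and 0.726 for each with an estimated correlation.

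The next comparison asks what differed within the mesenchyme-like cells alone. RFESD was 5.04 ± 0.51 (SE) log2 units higher in ligated cells (adjusted p = 0.00196), the histone gene H-10 (ENSGALG00010010791) 4.13 (adjusted p = 0.0103), the globin HBAD (ENSGALG00010019253) 4.76 (adjusted p = 0.0258) and TSPO2 (ENSGALG00010027621) 2.73 (adjusted p = 0.0413). These 4 genes also lead erythroid-like clusters, and the erythroid-like share was higher in each ligated library. SUSD3, another leading gene of those clusters, rose by 3.52 (adjusted p = 0.0103) at a mean under 20 CPM, and ENSGALG00010029469, without a symbol, fell by 2.60 (adjusted p = 0.0403). These last genes lie outside the naming rule and were named after their values were seen. Other genes named by the rule did not pass. TCF4, a transcription factor, had −1.58 log2 units (adjusted p = 0.0543), SHOX2 −1.67 (adjusted p = 0.208), RAVER1 −2.35 (adjusted p = 0.177), SSBP4 −1.27, SEPHS3 −1.42 and CS −1.26, while SIM2 had 1.60 (adjusted p = 0.0759). POSTN (0.22), VCAN (0.28), COL1A2 (0.07) and TWIST1 (0.21) differed by less than their standard errors (0.36, 0.31, 0.30 and 0.30). KLF2, a gene induced by blood flow, had −1.50 (adjusted p = 0.254).

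By edgeR's test 6 of 11792 genes passed, 5 higher and 1 lower, with 688 at an unadjusted p under 0.05. This fit kept called doublets, a choice made after the cell counts were seen. With called doublets removed, as planned, the day 5 sham library had 10 mesenchyme-like cells, and 0 genes passed (511 at an unadjusted p under 0.05), while at resolution 2 with doublets removed 5 genes passed (476). With doublets kept, the DESeq2 Wald test gave 36 genes (16 higher and 20 lower) and limma-voom 11 (6 higher and 5 lower). Without the day 5 pair 70 genes passed (34 higher and 36 lower) and without the day 6 pair 250 (85 higher and 165 lower). In cluster 0 alone at days 4 and 5, an alternative added after the data were seen, 352 genes passed with doublets kept and 9 with doublets removed. The 352 were 116 higher and 236 lower, and the 9 were 6 higher and 3 lower.

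Of the 21 lists, 8 passed in mesenchyme-like cells with camera's preset correlation, and adjusted p = 0.913 with an estimated correlation for each of them. By fry 0 of the 21 passed. It had called 7 of 10 simulated lists in these cells, in which every member was moved by 1 log2 unit. The lists that passed camera as lower here had medians from −0.88 to −0.18, so that rate need not hold for them. All 13 mitochondrially encoded genes were lower in ligated cells (median −0.88, adjusted p = 1.3e-06), with 0 that fell over all genes and 1 adjusted over the list alone. The share of barcodes over the mitochondrial limit was lower in the ligated libraries too. Heat shock and dissociation stress genes had a median of −0.48 (adjusted p = 0.00182), nuclear oxidative phosphorylation genes −0.23 (52 of 61 lower, adjusted p = 0.00255) and ribosomal protein genes −0.18 (62 of 68 lower, adjusted p = 0.00255). Flow response genes had −0.69 and neural crest regulators −0.36, each with an adjusted p of 0.0185. Notch pathway genes had −0.24 (adjusted p = 0.0310), with 0 that fell and 2 adjusted over the list alone. Globins had 4.59 (adjusted p = 2.3e-06), with 4 of 5 higher. Without the day 4 pair 2 lists passed. That pair differs in the make-up of the class, since only its ligated library held cluster 5 at resolution 1.

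Single days have 1 library per treatment, so the values that follow carry no test. In day 4 mesenchyme-like cells the Notch target genes NRARP and HES4 were lower in the ligated library, at 25.1 against 235 CPM and at 48.7 against 439 CPM. GADD45B stood at 15.3 against 122 CPM, TAGLN2 at 17.4 against 136 CPM and CYR61, a target of YAP, at 43.5 against 275 CPM. In cluster 0 alone, which both libraries share, NRARP stood at 28.8 against 237 CPM and HES4 at 53.1 against 422 CPM, while EBF2 stood at 308 against 64.0 CPM. SMOC1 stood at 453 against 30.8 CPM in all mesenchyme-like cells, and it leads cluster 5. The medians of the smooth muscle contractile (−0.93), neural crest (−0.58) and mitochondrially encoded lists (−1.43) lay below all 10000 random lists, and that of the Notch pathway (−0.60) at percentile 0.02. These positions reflect the spread between genes within 1 library per treatment, not the spread between libraries. The lists were not taken in cluster 0 alone. Cluster 5 held 42.8% of the ligated and 0 of the sham cells at resolution 1, so a difference in make-up is included. Barcodes over the mitochondrial limit were 40.2% of the sham library and 4.59% of the ligated library that day.

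At day 5, ESYT1 stood at 42.0 CPM in ligated and 2359 CPM in sham mesenchyme-like cells, RAVER1 at 221 and 2536 CPM, and TBX15 at 10.8 and 217 CPM, where the sham library had 20 such cells. RAVER1 was also higher in epithelium-like cells of the day 4 sham library, at 1446 against 259 CPM. At day 6, SOX9, a regulator of cartilage and glia, stood at 105 CPM in ligated and 20.5 CPM in sham mesenchyme-like cells. RSPO2, a WNT agonist, stood at 51.5 and 135 CPM, GATA6 at 55.4 and 144 CPM, NEFM at 54.4 and 147 CPM, and SERAF, a leading gene of the glia-like cluster, at 12.3 and 105 CPM. Extracellular matrix genes had a median of 0.37 at day 5 and −0.36 at day 6. Ribosomal protein genes had −0.35, −0.29 and 0.30 at days 4 to 6.

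**Figure D3:**
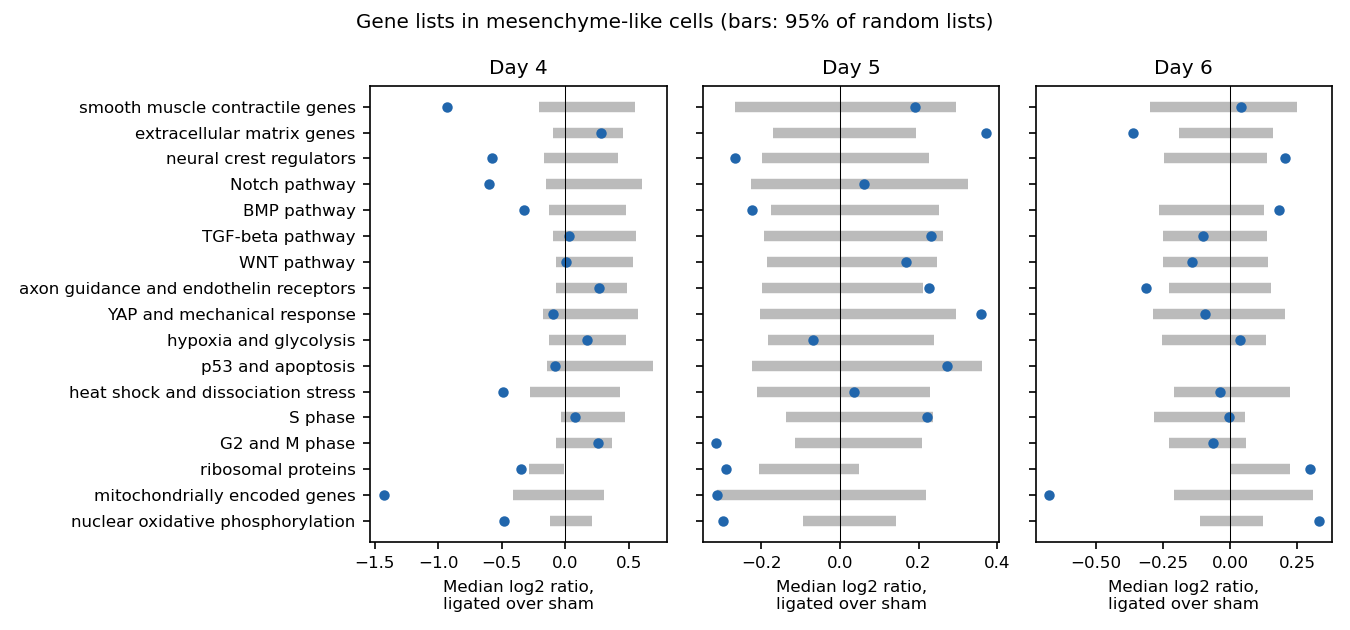
Points give the median log2 ratio of ligated over sham CPM of each gene list in mesenchyme-like cells at days 4, 5 and 6 (1 library per treatment and day), and bars the middle 95% of medians of 10000 random lists. The mitochondrially encoded list lies at −1.43 at day 4, and the ribosomal list goes from −0.35 at day 4 to 0.30 at day 6. The bars show the spread between genes, not between libraries.

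The series also follows the cells with age. When all cells of a library were summed, 7 of 8 measured epithelium markers were lower with age and 2 fell, or 4 adjusted over the list alone (adjusted p = 0.000765 by camera, adjusted p = 0.446 with an estimated correlation). CLDN3 fell by 2.20 log2 units per day (adjusted p = 0.0236) and EPCAM by 2.17 (adjusted p = 0.0354). The epithelium-like share of cells that were not erythroid-like was 9.68%, 36.1%, 0.865% and 0.524% in the sham libraries of days 4 to 7, and 19.3%, 12.5% and 0.405% in the ligated ones. NT5DC4 rose by 2.02 (adjusted p = 0.0492). POSTN had 2.38 per day (adjusted p = 0.0591) and IGDCC3 −1.64 (adjusted p = 0.0589), neither passing. By edgeR's test 12 of 14003 genes passed, 7 higher and 5 lower with age, with 2185 at an unadjusted p under 0.05. Without the day 4 sham or the day 6 ligated library 0 genes passed, without the day 4 ligated library 1, without the day 5 sham library 7, without the day 6 sham library 43 and without the day 7 sham library 33.

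Within mesenchyme-like cells, a comparison added after the data were seen, matrix genes rose with age. The class changed cluster over the same ages, with 99.4% of it in cluster 0 in the day 4 sham and 97.4% in cluster 6 in the day 7 sham library, so the slopes also set 1 cluster against another. POSTN (ENSGALG00010002373), a matrix protein of heart valves and fibroblasts, rose by 2.67 ± 0.36 (SE) log2 units per day (adjusted p = 0.00708), from 54.6 CPM in the day 4 sham to 6578 CPM in the day 7 sham library. COL1A2 rose by 0.90 (adjusted p = 0.0103). Of 29 measured extracellular matrix genes 20 rose, or 22 adjusted over the list alone, and none fell, while VCAN (0.23) and MFAP2 (0.19) did not pass. CCDC102B (2.74), MGAT4C (2.57) and NR4A3, an immediate early gene (2.40), rose as well. Among the 10 largest falls, LIN28B (−1.05, adjusted p = 0.00791) and TRIM71 (−1.06, adjusted p = 0.00206), which hold embryonic cells in an early state, fell, as did MYCN (−1.07), the chromatin remodeller CHD7 (−1.07), IGDCC3 (−1.44) and PRTG (−1.01). The Notch target HEY1 fell by 1.55 per day, DLX2 by 1.54, the hedgehog-binding HHIP by 1.38 and the neural crest factor TFAP2B by 1.13. The signal molecule WNT11, the leading gene of cluster 6, rose by 1.01 (adjusted p = 0.00708), DHRS3, which limits retinoic acid, by 1.23 (adjusted p = 0.00363) and the guidance cue SLIT3 by 0.80 (adjusted p = 0.0187).

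**Figure D4:**
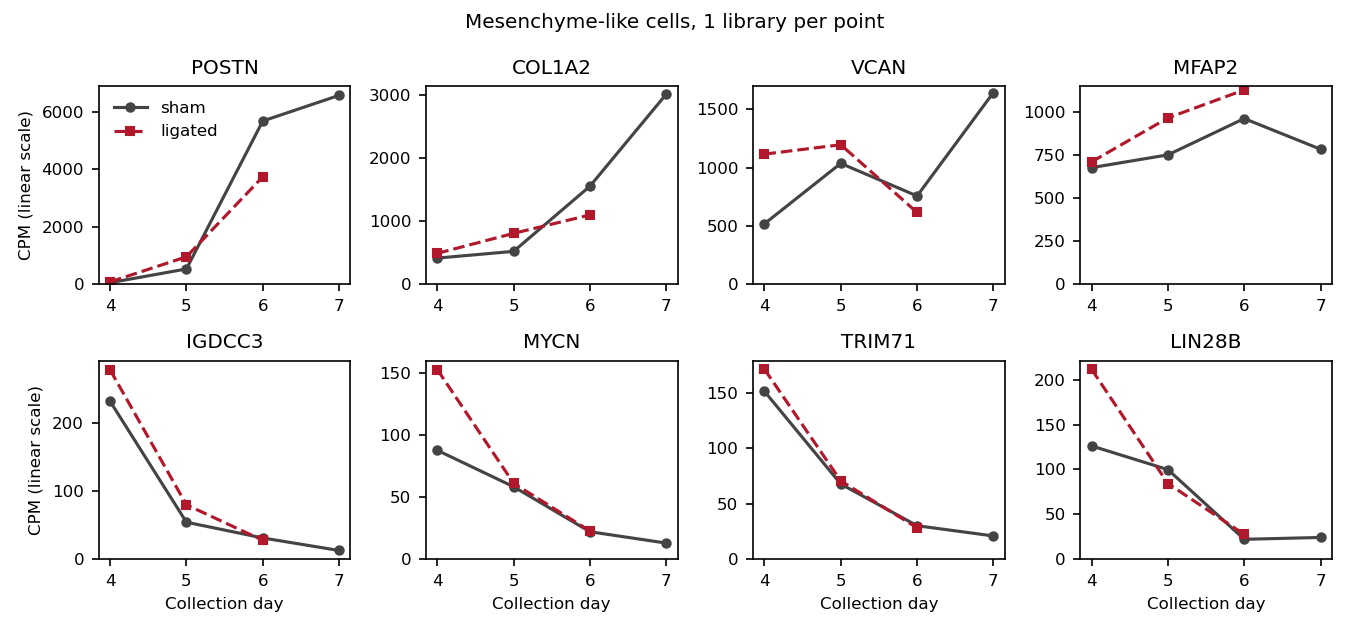
Lines give CPM of POSTN, COL1A2, VCAN, MFAP2, IGDCC3, MYCN, TRIM71 and LIN28B in mesenchyme-like cells against collection day on a linear scale, with 1 library per point, sham libraries solid and ligated libraries dashed. POSTN goes from 54.6 to 6578 CPM between the day 4 and day 7 sham libraries, and VCAN and MFAP2 did not pass the test.

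Cell cycle genes fell with age in these cells. Of 33 measured G2 and M phase genes 30 fell, or 33 adjusted over the list alone, among them TOP2A (−0.65 per day), HMGB2 (−0.61), TPX2 (−0.62) and CDK1 (−0.53). Of 28 S phase genes 15 fell, or 21 adjusted over the list alone, among them PCNA (−0.50), RRM2 (−0.65) and UHRF1 (−0.45). All 5 globins rose, in all-gene and list-alone counts alike, as did all 7 erythroid markers, and the erythroid-like share was higher in later libraries. Camera with its preset correlation gave an adjusted p of 2.1e-13 for matrix genes, 3.6e-20 for G2 and M phase, 1.2e-11 for S phase and 3.7e-05 for globins. In that order, adjusted p = 0.163, 0.206, 0.321 and 0.425 with an estimated correlation, and fry gave adjusted p values of 0.00291, 0.00424, 0.0206 and 0.0264. Of TGF-beta pathway genes 6 of 20 rose, and 6 adjusted over the list alone (SKI 0.51). Of retinoic acid genes 4 of 14 rose, and 5 adjusted over the list alone. Their adjusted p was 0.0141 and 0.00496 by camera, and adjusted p = 0.496 and 0.425 with an estimated correlation.

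By edgeR's test 1303 of 12152 genes passed for age in mesenchyme-like cells, 822 rising and 481 falling, with 3381 at an unadjusted p under 0.05. The count rests on the day 4 sham library: without it 41 genes passed, 35 rising and 6 falling, so at most 6 of the cell cycle genes kept their call, and POSTN, LIN28B, PRTG, HEY1 and DLX2 were among those that lost their call. Without the day 4 ligated library 549 passed, without the day 5 ligated 859, without the day 6 sham 640, without the day 7 sham 755 and without the day 6 ligated library 2188. With called doublets removed 643 passed.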

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

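The tests of explanations in this part were chosen after the results they measure had been seen. Among the 4 sham libraries, 8 of 34 tested sets of values had a library far from the other 3. The genes among these sets were picked after the data were seen, and some, such as ESYT1 and TBX15, already led the ratios of 1 day. No chance rate can therefore be set against this count. These libraries also differ in age, so a distant library is not a failed replicate.

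In the day 4 sham library the median kept cell had 6859 genes, against 1927 to 2476 in the other sham libraries. Mesenchyme-like cells of that library also had 237 CPM of NRARP and 104 CPM of HES5A. The day 5 sham library stood apart for ESYT1 (2424 CPM) and TBX15 (444 CPM), in 10 mesenchyme-like cells with called doublets removed. The day 6 sham library stood apart for FOS, at 1722 CPM in mesenchyme-like cells, and for leukocyte-like cells, at 8.07% of cells that were not erythroid-like. The day 7 sham library stood apart for smooth muscle-like cells, at 31.8% of such cells.

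Some differences between ligated and sham mesenchyme-like cells went opposite ways at different ages, and the difference between ages was not tested. At day 4 the make-up of the class differed too, since only the ligated library held cluster 5 at resolution 1. Extracellular matrix genes had a median log2 ratio of 0.37 at day 5 and −0.36 at day 6, and axon guidance and endothelin receptor genes 0.23 and −0.31. At days 4, 5 and 6 neural crest regulators had −0.58, −0.27 and 0.20, and BMP pathway genes −0.32, −0.22 and 0.18. Ribosomal protein genes had −0.35, −0.29 and 0.30, and nuclear oxidative phosphorylation genes −0.49, −0.30 and 0.33. Among cells that were not erythroid-like, the mesenchyme-like share differed by −16.5, 33.9 and 24.7 percentage points at days 4 to 6. The epithelium-like share differed by 9.59 and −23.7 points at days 4 and 5, and the unnamed share by 9.93 and −22.1 points. All these shares leave out called doublets, which numbered 10 in the day 4 sham and 19 in the day 5 sham library, but 1 in each ligated library.

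Barcodes removed for quality, which no comparison uses, also held the label transcript H2BRFP. They held 39 UMIs in the day 4 sham library (559 in kept cells), 9 in the day 4 ligated library (2447), 26 in the day 5 sham library (41) and 10 in the day 7 sham library (1934).

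The first pattern weighed is the presence of erythroid-like cells in libraries sorted for the label. Globin transcripts crowding out the label transcript is argued against: as CPM of UMIs other than globins, H2BRFP in erythroid-like cells of the day 6 ligated library was at 0% of its level in mesenchyme-like cells. Cells without the label transcript passing the sort stays open and suits the same values, since H2BRFP reached at most 9.88% of the mesenchyme-like level in any library with 20 cells of each class (upper limit 13.6%). A loss of the transcript in mature cells that keep the protein was not tested. Ligation also stays open: the erythroid-like share was higher in the ligated library at 3 of 3 ages, but the day 7 sham library had 62.6% of such cells without it.

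The second pattern is cluster 5, seen at resolution 1 in the day 4 ligated library and in no other. Too few sham cells is argued against: at the ligated share 66.4 cells were expected among the 155 sham cells and 0 were seen, with an upper limit of 1.94% in sham against a lower limit of 39.9% in ligated cells, and in the matching cluster at resolution 2 these limits were 8.20% and 52.95%. A candidate explanation is labelled crest of a more anterior axial level in that library, since HOX genes of paralog groups 3 to 5 summed to 4.27% of their level in cluster 0 of the same library. Ligation stays open: at resolution 1 the day 5 and day 6 ligated libraries together held 0 cluster 5 cells, whereas at resolution 2 they held 21 and 1 cells of the matching cluster. With 1 library per age and treatment, ligation and a difference in labelling or dissection cannot be told apart.

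The third pattern is the higher level of erythroid transcripts in ligated mesenchyme-like cells. Free RNA of erythroid cells is a candidate explanation: relative to erythroid-like cells, the 4 genes that rose and are not globins lay a median of 0.34 log2 units from the globins over 12 values, with the largest distance 1.02. Doublets with erythroid cells may add to it, since the median globin share per cell was 27.3% to 59.4% of the mean over the ligated libraries, between what many and what few carrying cells would give. A change within mesenchyme-like cells after ligation cannot be told apart from these, although the same genes were also higher in ligated epithelium-like cells at day 4 and glia-like cells at day 6, in 10 of 10 pairs of gene and class.

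Regroupings of the 6 libraries of days 4 to 6 into 3 and 3 number 10, too few for a share under 0.05. For all cells 1 of the 10, the real one, gave as many as 44 genes, and the highest other gave 0. For mesenchyme-like cells 5 of 10 groupings gave at least the real 6 genes, and the highest other gave 19. Those 4 other groupings divide only 1 of the 3 day pairs, so with day as a block they rest on that pair alone, and the groupings with 19 genes rest on day 5. Among the 4 that divide all pairs, as the real one does, the highest other gave 0.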

How the results depend on the processing

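The alternatives were planned, except those for age in mesenchyme-like cells and for genes at single days, the count of age genes without erythroid-like and leukocyte-like cells and the fits of cluster 0 alone at days 4 and 5, which were chosen after the data were seen. Counts were judged by a limit on their fold change, and shares by their sign alone. Of 130 counts and shares under alternatives, 48 counts moved beyond that limit and 5 shares changed sign. The other 77 are counts within the limit and shares that kept their sign, whatever their change in size. No named gene changed direction. The call was lost in 69 of 180 values of named ligation genes over all cells, 37 of 226 in mesenchyme-like cells, 29 of 156 for age over all cells and 29 of 235 for age in mesenchyme-like cells. A call was gained in 40 of 226 values for ligation in mesenchyme-like cells and in 22 of 156 for age over all cells. For each change below the cause was not tested, beyond what fewer cells, genes or libraries bring by construction.

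The 44 ligation genes over all cells became 663 with the DESeq2 Wald test, 2979 with limma-voom and 410 with no filter on low counts. They became 1 with libraries thinned to the smallest, 7 with doublets kept, 4 without erythroid-like and leukocyte-like cells and 252 with globin genes removed. Without the replicate block of day edgeR gave 0 (1872 at an unadjusted p under 0.05), and with day as a number over all 7 libraries it gave 0. Leaving out 1 day gave 15 to 3760 genes: 3760 without the day 4 pair, 15 without the day 5 pair and 32 without the day 6 pair.

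The 6 ligation genes within mesenchyme-like cells became 36 with DESeq2, 11 with limma-voom, 130 with no filter and 1 when thinned. Without the replicate block edgeR gave 0 (302 at an unadjusted p under 0.05), and with day as a number 0 (434). With doublets removed it gave 0 (511). The other changes of cells were made together with that removal: at least 200 genes per cell gave 0 (511), at most 10% mitochondrial UMIs 0 (510), resolution 0.5 0 (506), expression centred per library 0 (537) and resolution 2 gave 5 (476). In cluster 0 alone at days 4 and 5 it gave 352 with doublets kept and 9 with doublets removed, which takes the day 5 sham library from 19 to 10 cells. Leaving out 1 day gave 5 to 250 genes: 5 without the day 4 pair, 70 without day 5 and 250 without day 6.

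The 12 age genes over all cells became 940 with DESeq2, 2 when thinned and 325 without erythroid-like and leukocyte-like cells. In the 4 sham libraries alone edgeR gave 0 (2785 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 43, with 0 without the day 4 sham or the day 6 ligated library and 43 without the day 6 sham library. The 1303 age genes in mesenchyme-like cells became 2278 with DESeq2, 643 with doublets removed. Without cluster 5 they were 1258. Leaving out 1 library gave 41 to 2188, with 41 without the day 4 sham and 2188 without the day 6 ligated library.

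Of the 16 gene lists that passed camera over all cells and the 8 in mesenchyme-like cells, 0 passed with an estimated correlation and 0 with fry. Without the replicate block 16 and 6 passed. Leaving out 1 day gave 2 to 8 lists in mesenchyme-like cells, with 2 without the day 4 pair.

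The glia and Schwann precursor-like difference (−0.06 logit units) turned to 0.0923 with doublets kept and to 0.00379 at resolution 0.5. Leaving out 1 day gave −1.01 to 0.480: 0.351 without day 4 and 0.480 without day 6. The epithelium-like difference (−0.37) ranged from −0.949 to 0.135, the latter without day 5. The smooth muscle-like difference (−1.26) kept its sign with 1 day left out, at −0.569 without day 6 and −1.66 without day 5. At resolution 0.5 no cluster was named smooth muscle-like, so that alternative gives no value for this class. The effect of depth was tested by thinning alone, which brought the counts of 44, 6 and 12 genes to 1, 1 and 2.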

Other observations

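No explanation was tested in this part, and its classes and days were chosen after the data were seen. Erythroid-like cells of day 6 differed between libraries in their cell cycle and globin genes, in sham cluster 27 against ligated clusters 11, 12, 22 and 23. G2 and M phase genes had a median log2 ratio of ligated over sham of 3.55 (25 of 25 higher), S phase genes 1.95, hypoxia and glycolysis genes 2.49 (12 of 13 higher) and ribosomal protein genes 1.73 (67 of 68 higher). The median of all genes was 0.54. Mitochondrially encoded genes had −2.23 (13 of 13 lower) and globins −0.97 (4 of 5 lower). FOXM1, a regulator of mitosis, stood at 102 CPM in ligated and 1.74 CPM in sham cells, MXD3 at 258 and 4.75 CPM, and the heat shock gene HSPB9 at 1707 and 1.45 CPM. HBE1, a globin, stood at 108 CPM in ligated and 1731 CPM in sham cells. SERAF, the leading gene of the glia-like cluster, stood at 11.1 and 238 CPM. Of all globin UMIs in erythroid-like cells, HBE1 made up 1.67% in the day 7 sham library and at most 0.2496% in the others, and HBZ 14.4% in the day 7 sham library against 30.8% to 42.3% in the others, of which the day 4 and day 5 sham libraries had 1 and 6 such cells.

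Glia and Schwann precursor-like cells of day 6 (116 sham and 34 ligated cells) had HSPB9 at 660.3 CPM in ligated and 29.3 CPM in sham cells, STMN2, a gene of growing neurites, at 276 and 36.8 CPM, CDKN1C, which slows the cell cycle, at 342 and 76.6 CPM, and BAG3 at 166 and 38.0 CPM. ADGRB3 stood at 223 and 1041 CPM, CRABP1, which binds retinoic acid, at 159 and 483 CPM, and CDC20 at 49.3 and 121 CPM. Epithelium-like cells of day 4 (24 sham and 480 ligated cells) had RUNX1 at 42.0 CPM in ligated and 340 CPM in sham cells, ATP10B at 60.0 and 361 CPM, and TLL1 at 150 and 11.9 CPM.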
